A study of Homo sapiens with 2 samples.

How the data were processed

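RNA sequencing of 2 libraries was used, 1 from the 786-O line and 1 from its SETD2 knockout, and each was assigned to its group by its labels. Per the labels' protocols, total RNA was extracted by conventional methods and libraries were made with standard Illumina protocols. The authors deposited 1 table per library with a raw read count and an RPKM value for each gene, per the file headers. Per the submitters' processing notes, hg19 was the genome build and TopHat2 2.0.6, Bowtie and HTSeq were used. Their settings, the annotation release and whether counting used strand are not given in the sources used here. Reads of a gene and of an overlapping antisense gene can therefore not be told apart.

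Each table held 23398 rows with hg19 coordinates. The deposited count was even in every row of both tables, so that each fragment appears to enter as 2 reads, and counts were divided by 2 to obtain fragments. This departs from the design, which assumed that 1 count was 1 read, and the undivided counts were tried as an alternative. The deposited RPKM was the count divided by the gene's length and by 1 library total per table, of which the counts in the wild-type and knockout tables made up 72.7% and 72.9%. RPKM values are quoted for SETD2 only. Of 23 genes with a row on X and a row on Y, 22 had the same count in both rows, 19 of them above 0, so reads that match several places appear to be counted at each of them. The Y rows of these genes were dropped, which left 23375 rows. The tables held 0 rows of mitochondrial DNA, and the list of genes encoded there was not analysed here. Biotypes came from RefSeq gene records by symbol and were found for 94.2% of rows, with older symbols matched through their synonyms. GC content was that of the longest GENCODE 29 transcript with the gene's symbol. No coordinates were taken from either source, and GENCODE 29 is on another build.

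The wild-type table summed to 124729756 reads or 62304084 fragments and the knockout table to 101423332 reads or 50670012 fragments. At least 1 fragment was counted for 17896 and 18396 genes, and the 10 most abundant genes took 5.34% and 5.45%. A floor of 3 fragments was used for genes at 0 in one library, and folds against it allow for the counting error of that library alone. The exact intervals, which allow for both libraries, start lower and are given beside these folds.

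Libraries were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, on the 16894 genes with at least 10 reads over both libraries. Per gene, the ratio of scaled fragments was given its exact conditional (Clopper-Pearson) 95% interval, and log2 ratios used 0.5 added fragments per library. A gene was counted as higher or lower when its whole interval lay beyond 2-fold. No p-value was computed, because 1 library per group gives no replicate error. List members were counted at 1.5-fold, and each list's median log2 ratio was compared with 10000 random lists of the same size drawn from 20 bins of abundance. The 44 lists held 1030 entries, of which 1006 were found. Chromosomes, gene classes and consecutive blocks of 50 genes with at least 100 reads were described in the same way. A lower stretch was at least 3 consecutive blocks with medians below -0.3. Chromosome arms were planned but not computed, since no hg19 centromere positions were used here.

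The lists and most alternatives were fixed before the data were examined. The undivided counts, the ratio relative to the median of the 50 nearest expressed genes, the block analysis, the gene families and both tests of genes near 0 in one library were chosen after seeing the data. Named genes were SETD2, the 15 protein-coding genes with the highest and the 15 with the lowest ratio, and the 3 highest and 3 lowest non-coding genes. These were ranked by the interval bound nearest to 1 among genes with at least 200 reads in the higher library. To these were added up to 2 higher and 2 lower members of each list, the 3 most abundant markers of other cell types, and VHL, EPAS1, HIF1A, PBRM1 and BAP1. Lists without a counted member were given by their 2 most abundant genes. Some genes and 1 list that these rules take are not reported here. Alternatives were total count and upper quartile scaling, DESeq2 1.42.0 median-of-ratios size factors, minimums of 1 and 50 reads, a 99% interval, the fold without an interval, protein-coding genes only, 2 added fragments, 10 bins and list means.

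The counting rule was tested on simulated data drawn from the means and depths of these libraries for the knockout against wild-type comparison, with 200 of 16894 genes changed. With counting error alone, 3 unchanged genes passed, 100% of genes changed by 4-fold and 100% of those changed by 8-fold were recovered, and 95.6% of intervals held the true ratio. With an assumed coefficient of variation between cultures of 20%, 0.59% of unchanged genes passed and 41.0% of intervals held the true ratio. With 40%, 13.8% of unchanged genes passed and 85% of 4-fold changes were recovered. The spread between cultures of these lines was not measured here. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.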

Results

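RNA from the human renal carcinoma line 786-O and from an isogenic SETD2 knockout line was sequenced, with 1 library of each line. 786-O is an established clear cell renal carcinoma line without functional VHL. The knockout line was made with a zinc finger nuclease, a designed protein that cuts DNA at a chosen site. SETD2 is the methyltransferase that places the trimethyl mark of H3K36 along transcribed genes, and it is recurrently mutated in clear cell renal carcinoma. The comparison asks which transcripts differed between the lines with and without intact SETD2. The wild-type library held 62304084 fragments in genes and the knockout library 50670012, and 3 fragments corresponded to 0.0494 and 0.0577 CPM, the count relative to the TMM-scaled library size. With 1 library per line, the differences had no replicate check, and each compares these libraries rather than the conditions. Intervals given below are exact 95% counting intervals and cover counting error only.

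SETD2 itself was lower in the knockout library. Its transcripts (hg19 chromosome 3, 47057898 to 47205467) were counted in 4908 wild-type fragments, or 80.9 CPM, and in 1404 knockout fragments, or 27.0 CPM. The ratio of knockout to wild type was 0.334, with an interval of 0.314 to 0.354, and the authors' RPKM values were 6.79 and 2.39. The block of 50 expressed genes that holds SETD2 (42.6 to 48.5 Mb) had a median log2 ratio of -0.07, against -1.58 for SETD2. Of the other genes that define the background of the line, VHL had a ratio of 1.09 and BAP1, a nuclear deubiquitinase, a ratio of 1.25. EPAS1, a hypoxia-inducible transcription factor subunit, had a ratio of 0.553, HIF1A a ratio of 0.612, and PBRM1, a subunit of a chromatin remodelling complex, a ratio of 0.575. The position of the nuclease lesion was not analysed here.

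The transcripts that were most strongly lower in the knockout library included epithelial, membrane and secreted proteins. KRT19 (chromosome 17, 39679869 to 39684641), a keratin of simple epithelia, was counted in 6757 wild-type and 6 knockout fragments, a 965-fold lower level with an interval of 443-fold to 2632-fold. ANPEP, a brush border aminopeptidase, was 374-fold lower, LIPG, an endothelial lipase, 103-fold lower, and NID1, a basement membrane protein, 140-fold lower. CXCL5 (chromosome 4, 74861359 to 74864416), a neutrophil-attracting chemokine, was at 175 CPM in the wild-type and 2.42 CPM in the knockout library, 72.3-fold lower with an interval of 60.6-fold to 86.9-fold. No knockout fragment was counted for ULK2, an autophagy kinase, GSTM4, a glutathione transferase, or IGFBP1, a binding protein of insulin-like growth factors. Against a floor of 3 fragments in that library, these genes were at least 215-fold, 191-fold and 131-fold lower, and their exact intervals start at 175-fold, 155-fold and 106-fold. Of the other genes among the 15 most strongly lower, SYT13, a synaptotagmin, had a ratio of 0.00735. TLR2, a pattern recognition receptor, had 422 and 1 fragments (interval of the ratio 6.98e-05 to 0.0155), and P2RY2, a nucleotide receptor, had 395 and 2 (0.000713 to 0.0215). DNAJC15 had 837 and 3 fragments (0.00086 to 0.0123), EFCAB4B 555 and 2 (0.000508 to 0.0152), ADM2 348 and 1 (8.46e-05 to 0.0188) and SPINT1 371 and 2 (0.000759 to 0.0229).

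In the other direction, COL22A1 (chromosome 8, 139600478 to 139926236), a collagen of tissue junctions, was counted in 405 knockout fragments and in no wild-type fragment, at least 157-fold higher against the floor of 3 wild-type fragments (exact interval from 127.5). RSAD2 (chromosome 2, 7017796 to 7038363), an interferon-induced antiviral protein, had 31 wild-type and 2352 knockout fragments, an 88.5-fold ratio with an interval of 62.2 to 131. DSP, which encodes the desmosomal protein desmoplakin, was 33.6-fold higher, and OSBPL1A, an oxysterol-binding protein, 50.5-fold higher. UNC5A, a netrin receptor, was 76.1-fold higher, PSG1, a pregnancy-specific glycoprotein, 56.1-fold higher, and ALOX5, the lipoxygenase that starts leukotriene synthesis, 38.8-fold higher. The MHC class II genes HLA-DRB1 and HLA-DQB1 had 5 and 1 wild-type fragments and 544 and 257 knockout fragments, ratios of 127 (interval 54.1 to 392.4) and 300 (53.3 to 11885). Also among the 15 most strongly higher genes were CRISPLD1, ZNF704, KIF26A, MARK1, RRAGD and GHR. Their ratios were 485 (interval 86.6 to 19210), 176 (48.3 to 1461), 106, 183 (32.4 to 7278), 40.7 and 135 (23.8 to 5389). Counts of genes with near-identical copies, such as HLA, PSG, histone, protocadherin and metallothionein genes, are uncertain, because reads can be shared between copies.

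Of 16894 genes tested, 971 had an interval wholly above 2-fold in the knockout library and 569 an interval wholly below 0.5-fold. The 1540 genes made up 9.12% of those tested, and 63.1% of them were higher. In the simulation, 0.59% of unchanged genes passed this rule at an assumed variation between cultures of 20%, and 13.8% at 40%. As that variation was not measured, the share alone does not separate an effect of the knockout from differences between cultures. Among protein-coding genes, 883 were higher and 549 lower. The interval lay wholly beyond 8-fold for 107 higher and 85 lower genes. Of non-coding genes, HLA-H, an HLA pseudogene, was 45.3-fold higher, and the imprinted transcript H19 was counted in 1 wild-type and 103 knockout fragments (ratio 120, interval 21.1 to 4791). HCG26 had 1 and 139 fragments (ratio 162, interval 28.6 to 6449). The metallothionein pseudogene MT1L was counted in 874 wild-type and 2 knockout fragments (ratio 0.00267, interval 0.000323 to 0.00967). MEIS3P1 and SLC26A10 were lower with ratios of 0.0614 and 0.307.

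**Figure D1:**
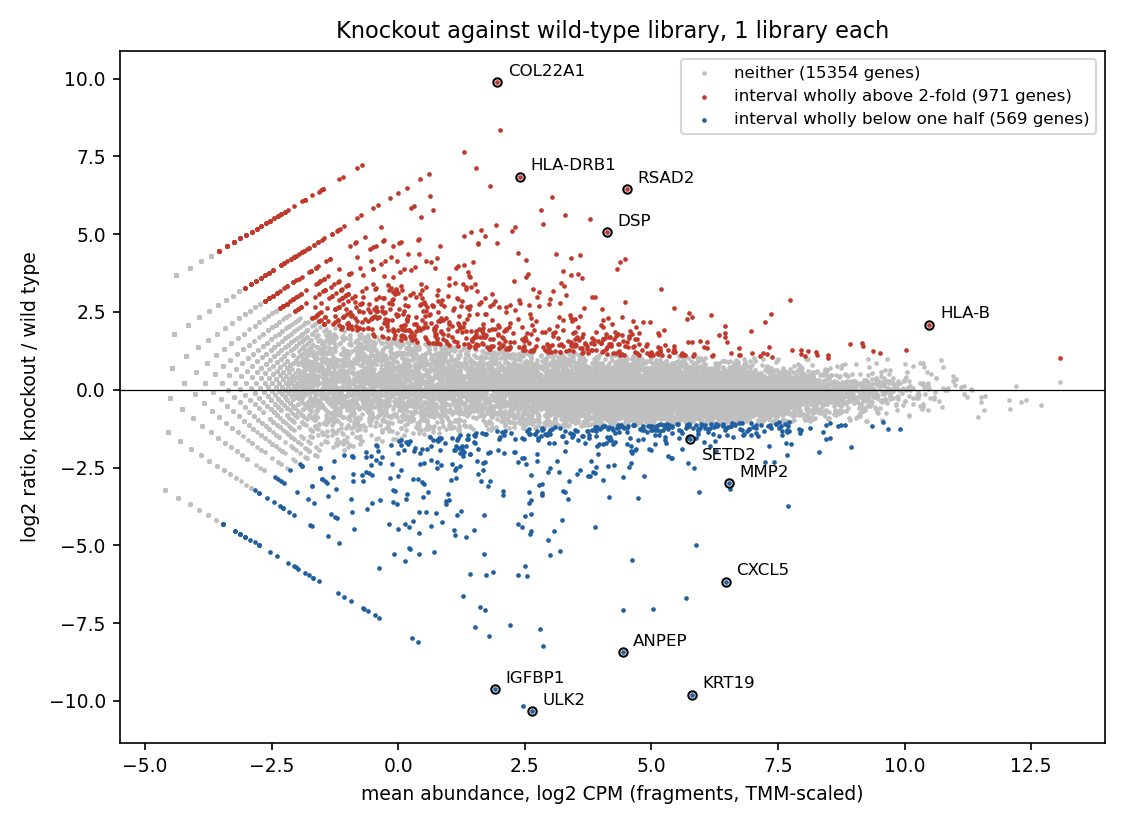
Log2 ratio of knockout to wild type (vertical axis) against the mean abundance in log2 CPM (horizontal axis) for 16894 genes, 1 library per line. Red points are the 971 genes with a counting interval wholly above 2-fold, blue points the 569 wholly below 0.5-fold, and SETD2 lies among the blue points at -1.58.

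The gene lists below describe these libraries only. A member counted as higher or lower had an interval wholly beyond 1.5-fold, and each list's median log2 ratio was placed among 10000 random lists of genes of matched abundance. Of 42 lists with at least 5 measured members, 8 had a median above and 10 a median below the central 95% of random lists. By chance, 2.1 lists would be expected outside if the members varied independently. Members of a list can vary together and some lists share genes, so more can lie outside between any such libraries.

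Inflammatory cytokines and NF-kB targets were lower together. Of 22 measured members, 20 were lower and 0 higher, and the median log2 ratio of -1.61 was at percentile 0 of random lists. Besides CXCL5, the cytokine TNF was counted in 386 wild-type and 8 knockout fragments, 41.4-fold lower with an interval of 20.8-fold to 96.5-fold. Interferon-stimulated genes had the opposite sign, with 17 of 33 members higher, 1 lower and a median of 0.75 at percentile 100. OASL, an interferon-induced relative of the oligoadenylate synthetases, was 8.80-fold higher next to RSAD2, while GBP2, an interferon-induced GTPase, had a ratio of 0.573. Antigen presentation by MHC class I included 8 higher and 0 lower genes of 14, with a median of 0.86 at percentile 100. HLA-B was 4.26-fold higher (interval 4.21 to 4.31).

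Genes of mitosis, DNA replication and homologous recombination had lower medians. Of 27 mitosis genes, 7 were lower and 0 higher (median -0.49, percentile 0.01), among them NUF2, a kinetochore protein, at a ratio of 0.464 and ANLN, a cytokinesis protein, at 0.553. Of 28 genes of DNA replication and nucleotide supply, 6 were lower and 1 higher (median -0.42, percentile 0.06). MCM7, a subunit of the replicative helicase, had a ratio of 0.458 and CDC45, its partner at the fork, 0.537, whereas RRM2B, a ribonucleotide reductase subunit, had a ratio of 1.95. Of 24 genes of homologous recombination repair, 5 were lower and 0 higher (median -0.48, percentile 0.01). XRCC2, which acts in strand exchange, had a ratio of 0.487. Of 12 DNA mismatch repair genes, 0 were higher and 0 lower, with a median of -0.10 at percentile 38.9. Its most abundant members, MSH6 and PCNA, had ratios of 0.876 and 0.922.

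Hypoxia-inducible factor targets were lower by a small median, -0.30 at percentile 0.755, with 7 of 29 members lower and 0 higher. LOX, a collagen cross-linking enzyme, was 8.39-fold lower (interval 6.62-fold to 10.8-fold), and VEGFA, an angiogenic growth factor, had a ratio of 0.511. Glycolysis enzymes had 8 of 17 members lower and a median of -0.40 at percentile 0.35, with ENO2 at a ratio of 0.306 and ALDOC at 0.285. ENO2 lies in a stretch of chromosome 12 whose genes were lower together, and relative to the 50 nearest expressed genes the glycolysis median was -0.16, at percentile 9.76. Of 23 genes of the integrated stress response and the unfolded protein response, 10 were lower and 2 higher (median -0.59, percentile 0.01). ASNS, asparagine synthetase, had a ratio of 0.220 and PDIA4, a protein disulfide isomerase, 0.450, whereas SESN2, a stress-induced protein, had 1.84. PHGDH, the first enzyme of serine synthesis, had 1 wild-type and 36 knockout fragments (interval 7.07 to 1704). The mean of this list, -0.26, lay inside the range of random lists at percentile 7.09, and relative to neighbouring genes its median was -0.34, below the range at percentile 0.05.

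Genes of the cell surface and matrix moved in both directions. Among 30 collagens and matrix genes, 9 were higher and 10 lower, with a median of 0.36 at percentile 99.9 but a mean of -0.14. COL12A1 was 4.59-fold and POSTN 11.1-fold higher (interval 3.99 to 42.7), while COL6A3 was 13.2-fold and COL5A2 6.47-fold lower. Of 22 clustered protocadherins, 9 were higher and 1 lower, with a median of 1.34 at percentile 99.8. PCDHB15 had 0 wild-type and 22 knockout fragments, at least 8.55-fold higher against the floor (exact interval from 6.39), PCDHB3 was 8.40-fold higher, and PCDHB2 had a ratio of 0.324. Of 19 epithelial genes, 2 were higher and 6 lower. Beside DSP and KRT19, the adhesion molecule EPCAM was 28.1-fold lower and the cadherin CDH6 had a ratio of 1.99. The list's median of -0.10 lay inside the range and its mean of -0.78 below it, at percentile 0.12. Of 18 mesenchymal genes, 5 were higher and 4 lower (median -0.01, inside the range). ACTA2, smooth muscle actin, was 3.07-fold and SNAI1, a transcription factor, 2.75-fold higher, MMP2, a gelatinase, was 8.01-fold lower, and CALD1, an actin-binding protein, had a ratio of 0.494. Matrix proteases and their inhibitors had 3 higher and 5 lower members of 24 (median -0.08, inside the range). MMP15 was 2.86-fold and TIMP2 2.05-fold higher, and ADAMTS12 was 26.6-fold lower.

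Nephron genes were measured in part. Of 16 proximal tubule genes, 4 were higher and 4 lower (median -0.16, inside the range). The list lay below the range with at least 50 reads (median -0.33, percentile 2.31), as a mean (-0.52, percentile 1.53) and relative to the 50 nearest expressed genes (median -0.36, percentile 0.51). The water channel AQP1 was 3.09-fold and the glucose transporter SLC5A2 3.01-fold higher (interval 1.74 to 5.41), and the peptidase MME was 5.42-fold lower beside ANPEP. Of 6 distal nephron genes, 1 was higher and 3 lower, with a median of -1.42 at percentile 0.32. The water channel AQP3 was 11.9-fold lower, and GATA3 had 17 wild-type and 0 knockout fragments, at least 4.86-fold lower against the floor (exact interval from 3.54-fold). CALB1, which encodes calbindin, had 0 wild-type and 20 knockout fragments. With genes of 1 read or more the distal median was 0.28, at percentile 39.5, and the mean of the list, -0.59, was at percentile 5.55, both inside the range. Of 21 kidney developmental transcription factors, LHX1 was 2.64-fold higher and GATA3 was the 1 lower gene (median 0.34, inside the range).

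Markers of other cell types were low or moved in both directions. Of 18 leukocyte markers, 9 were measured, 3 of them higher and 1 lower, with a median of 0.71 inside the range. LCP1, an actin-bundling protein, was 5.44-fold higher, at 277 CPM in the knockout library, CSF1R had a ratio of 0.401, CD68 a ratio of 1.03, and CD14 was 6.33-fold higher at 0.730 CPM. Of 11 measured endothelial markers, 3 were higher and 1 lower (median 1.12, inside the range), with EGFL7 2.93-fold higher, ERG at 3 and 22 fragments (interval 2.57 to 44.6), ESAM at a ratio of 1.30 and ROBO4 at 0.413. Of 11 fibroblast and pericyte markers, 2 were higher and 3 lower (median 0.36, inside the range). COL1A1 was 2.25-fold higher, LUM had a ratio of 0.367, RGS5 a ratio of 1.29, and COL1A2 had 14 wild-type and 0 knockout fragments.

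Signalling genes differed individually. Of 25 Wnt pathway genes and targets, 8 were higher and 8 lower (median 0.16, inside the range). NKD1, a feedback inhibitor of the pathway, was 10.5-fold and the receptor FZD2 2.84-fold higher, whereas the ligands WNT3 and WNT5A were 6.98-fold and 3.33-fold lower. Among 32 receptor tyrosine kinases and ligands, 2 were higher and 6 lower, with a median of -0.28 at percentile 0.74. With at least 50 reads this median was -0.11, inside the range at percentile 21.5. FGFR1 had a ratio of 1.99 and EPHB4 was 2.39-fold higher. The growth factor AREG was 7.40-fold lower, and IGFBP5 had 19 wild-type and 1 knockout fragments (ratio 0.0614, interval 0.00148 to 0.386). Of 23 TGF-beta pathway genes, 3 were higher and 4 lower (median 0.03), with CTGF 2.12-fold higher, BMP2 at a ratio of 1.96, BAMBI at 0.310 and SMAD3 at 0.397. YAP targets had 1 higher and 1 lower gene of 20, CTGF and F3 (ratio 0.362), and a median of 0.13 at percentile 97.4. The list lay above the range when matched in 10 bins of abundance (percentile 97.6), as a mean (0.24, percentile 98.6) and relative to neighbouring genes (median 0.19, percentile 99.4). Of 23 immediate early genes, 2 were higher and 5 lower (median -0.07), with FOSB 3.97-fold and KLF4 2.02-fold higher, IER3 at a ratio of 0.428 and KLF6 at 0.452. These medians, other than that of the receptor tyrosine kinase list, lay inside the range.

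Among genes of metabolism and transport, 4 of 21 autophagy and lysosome genes were higher and 0 lower (median 0.31, percentile 99.98). The list does not hold the autophagy kinase ULK2, which had 754 wild-type and 0 knockout fragments. ATG16L1, which acts in autophagosome formation, was 2.15-fold higher, and the lysosomal protease CTSD had a ratio of 1.80. Of 21 solute carriers and ion channels, 1 was higher and 7 lower (median -0.39, percentile 0.56, and -0.24 at percentile 1.56 relative to neighbouring genes), with ABCC3 2.12-fold higher, ABCB1, a drug efflux pump, at a ratio of 0.404 and SLC38A1 at 0.460. Lipid storage and fatty acid metabolism had 3 higher and 3 lower genes of 24 (median -0.00304), with PPARGC1A 2.86-fold and the lipid droplet protein PLIN2 2.03-fold higher, and the desaturases FADS1 and FADS2 at ratios of 0.599 and 0.477. Of 19 genes of cholesterol synthesis, 0 were higher and 2 lower (median -0.19), INSIG1 at a ratio of 0.557 and FDPS at 0.641, and relative to neighbouring genes the median had the opposite sign, 0.05. Of 34 nuclear-encoded respiratory chain genes, 0 were higher and 1, NDUFA9 (ratio 0.447), was lower (median 0.07). The lipid, cholesterol and respiratory chain medians lay inside the range.

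Of 16 clear cell renal carcinoma driver genes other than SETD2, 1 was higher and 1, PBRM1, was lower, with a median of 0.09 inside the range, and relative to neighbouring genes 0.15, above it at percentile 98.0. Of 23 genes of the H3K36 methylation machinery other than SETD2, 1 was higher and 2 lower, with a median of 0.07 inside the range. DNMT3B, a DNA methyltransferase that binds methylated H3K36, was 2.33-fold higher, WHSC1, which dimethylates H3K36, had a ratio of 0.548, and ZMYND11, a reader of the trimethyl mark, had 0.602. Relative to the 50 nearest expressed genes, the log2 ratio of ZMYND11 was -0.14 instead of -0.73. Of 30 replication-dependent histone genes, 12 were higher and 0 lower (median 0.82, percentile 99.01). HIST1H2BK was 9.49-fold higher (interval 8.57 to 10.5) and HIST1H3E had 1 and 49 fragments (interval 9.79 to 2303). Relative to the 50 nearest expressed genes, the histone median was 0.51, at percentile 85.1, and the list also lay inside the range with genes of 1 read or more (median 0.64, percentile 96.2) and as a mean (0.90, percentile 95.8). All 52 measured genes with HIST symbols, a group chosen after the data were seen, had a median of 0.22 at percentile 31.4. Of 50 ribosomal protein genes, 0 were higher and 1, RPL5 (ratio 0.592), was lower. Their median was 0.08 at percentile 99.67, and relative to neighbouring genes 0.02 at percentile 91.7, while their mean was 0.03 at percentile 95.9. Of 30 splicing factors, 0 were higher and 1, PTBP2 (ratio 0.485), was lower (median -0.09). Of 15 tubulins, TUBA1A was 3.51-fold higher and TUBA4A had a ratio of 1.75, with TUBA1C and TUBB3 at 0.642 and 0.632 (median -0.10). Of 14 nuclear long non-coding RNAs, 2 were higher and 0 lower (median 0.31), H19 and HOTTIP, the latter with 1 and 10 fragments (interval 1.66 to 506). Their mean of 0.81, at percentile 98.98, and their median relative to neighbouring genes, 0.35 at percentile 98.3, lay above the range. Of 33 HOX genes, 2 were higher and 1 lower (median 0.14), with HOXA13 2.84-fold and HOXD3 2.04-fold higher and HOXB13 at 9 and 0 fragments. Of 9 measured cancer-testis genes, 1 was lower, MAGEA3 with a ratio of 0.0993 (median -0.25, a mean of -0.89 below the range at percentile 0.97, and a median of 0.30 relative to neighbouring genes, inside it). Of 27 housekeeping genes, 0 were higher and 3 lower (median -0.19, and -0.12 relative to neighbouring genes), among them GAPDH at a ratio of 0.541 and GUSB at 0.579. The medians of the splicing, tubulin, long non-coding, HOX, cancer-testis and housekeeping lists lay inside the range. Of small structural RNAs, 4 were measured, with RPPH1 at a ratio of 0.494.

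**Figure D2:**
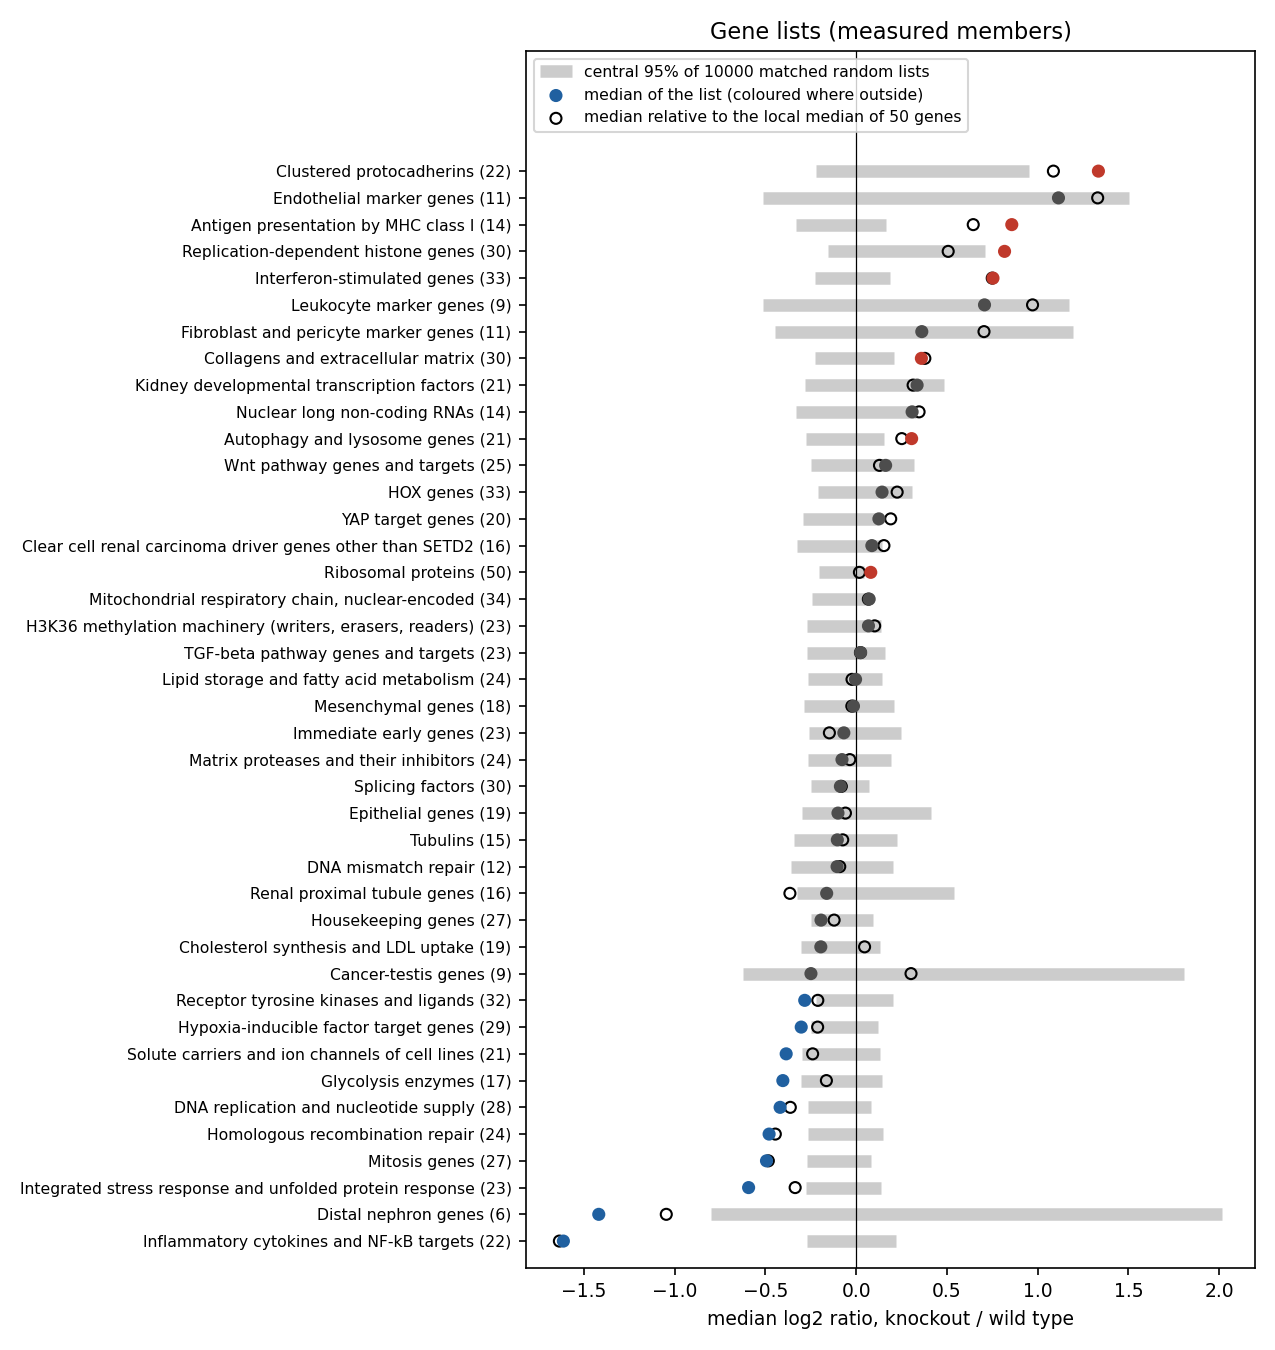
Median log2 ratio of knockout to wild type (horizontal axis) of gene lists with at least 5 measured members, whose number stands in parentheses. Filled circles are list medians (red above, blue below, grey inside the range of random lists), grey bars the central 95% of 10000 matched random lists and open circles the medians relative to the 50 nearest expressed genes; inflammatory and NF-kB genes lie lowest at -1.61.

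Genes were lower together along several chromosomes. The median log2 ratio was -0.50 on chromosome 7, where 74.5% of genes lay below 0, -0.48 on chromosome 12, where 78.0% did, and -0.19 on chromosome 1. Chromosome 16 had the highest median, 0.23. Chromosomes 5, 6, 8, 9, 13, 19 and 20, with medians between 0.14 and 0.19, were like it at percentile 100 of matched random lists. Chromosomes 1, 7, 10, 12 and X were at percentile 0. In blocks of 50 expressed genes, 5 stretches of at least 3 consecutive blocks had medians below -0.3. They were chromosome 1 at 84.9 to 146.7 Mb (median -0.65) and at 151 to 221 Mb (-0.39), chromosome 7 at 44.8 to 159 Mb (-0.65), and chromosome 12 at 0.0880 to 62.8 Mb (-0.59) and at 76.7 to 134 Mb (-0.47). The stretches held 1762 genes, 12.9% of the genes in blocks, with 36.7% of the lower genes there (185 of 504) and 6.80% of the higher genes (47 of 691). The median inside them was -0.54 and outside them 0.03. The stretches were defined by low medians of these same ratios, so such differences follow in part from that choice. Runs of fewer than 3 blocks with medians below -0.3 lay on chromosome 10 at 0.180 to 13.5 Mb (-0.63, with 84% of genes below 0) and 13.6 to 28.6 Mb (-0.48, 78%), on X at 150 to 155 Mb (-0.46, 83.6%), on chromosome 7 at 24.6 to 33.0 Mb (-0.41) and on chromosome 11 at 47.7 to 61.6 Mb (-0.30). Of the genes named above, 24 that were lower by the list rule lie in the blocks of these stretches, and relative to the 50 nearest expressed genes the log2 ratios of 18 of them came closer to 0 by a factor of over 1.5. On chromosome 1 these were F3 (-0.65 relative to neighbours), GBP2 (-0.29), FDPS (-0.29), PTBP2 (-0.23) and RPL5 (-0.10). On chromosome 7 they were ASNS (-1.40), ABCB1 (-0.63), PDIA4 (-0.45), CALD1 (-0.40), XRCC2 (-0.39), MCM7 (-0.36), INSIG1 (-0.20) and GUSB (-0.17), and on chromosome 12 ENO2 (-0.89), SLC38A1 (-0.59), NDUFA9 (-0.29), TUBA1C (-0.17) and GAPDH (-0.02). The other 6 were GSTM4, NUF2, IGFBP1, EFCAB4B, SLC26A10 and LUM. Outside the stretches, ANLN, at -0.48, and KLF6 (-0.55) and ZMYND11 (-0.14), both in the first of the chromosome 10 blocks, came closer to 0 by such a factor.

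**Figure D3:**
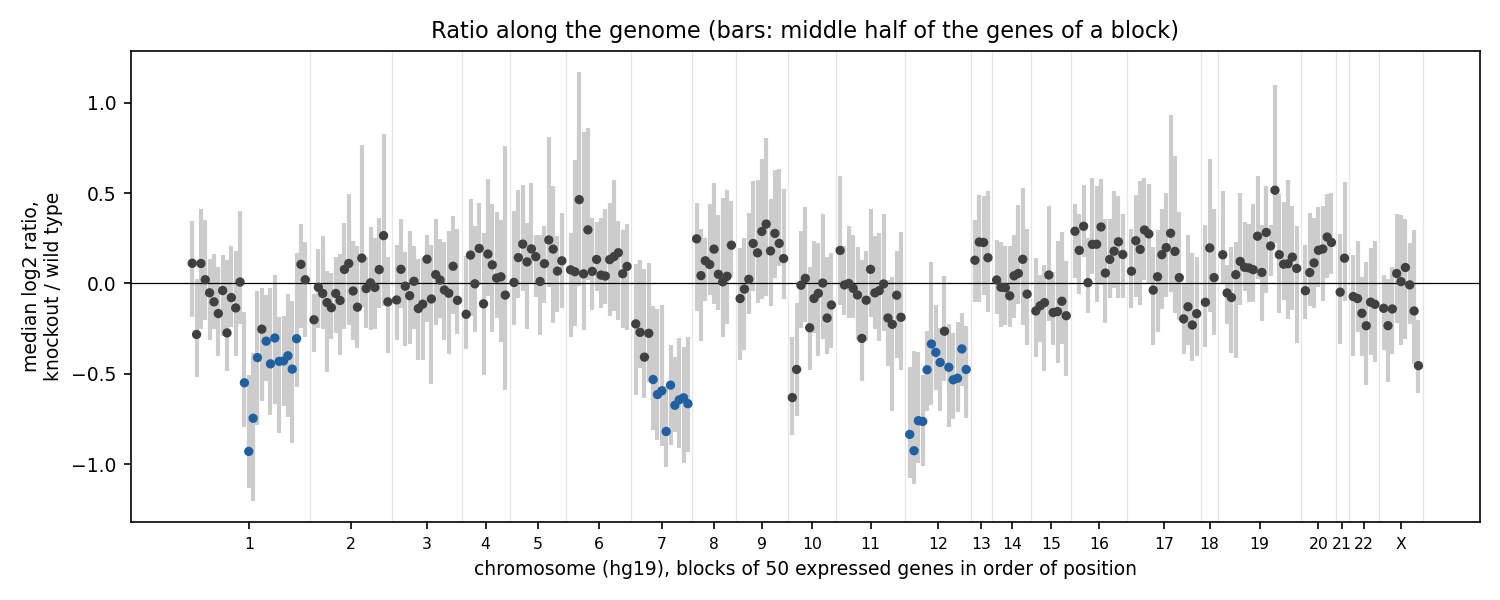
Median log2 ratio of knockout to wild type (vertical axis) in consecutive blocks of 50 expressed genes along chromosomes 1 to 22 and X (horizontal axis, hg19). Points are block medians, blue in the 5 lower stretches, and grey bars span the middle 50% of the genes of a block; block medians reach down to -0.93 on chromosome 1.

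By class, the 499 zinc finger genes with ZNF symbols had a median log2 ratio of 0.19, at percentile 100 of matched random lists. Of them, 27 were beyond 2-fold higher and 8 lower. Over all tested genes these shares were 5.75% and 3.37%, so ZNF genes had no excess of higher genes and fewer lower ones. The 239 of them on chromosome 19 had a median of 0.23, where all genes of chromosome 19 had 0.18. Across 5 classes of genomic span the medians lay between -0.01 and 0.05, and across 5 classes of exon length between -0.05 and 0.04. Against random lists of matched abundance, the shortest exon length class was at percentile 0 and the longest at 100, and the shortest span class was at percentile 0.285 and the longest at 99.98. In the shortest and the longest class, genes beyond 2-fold higher numbered 114 and 258 by exon length and 140 and 316 by span. Lower genes numbered 80 and 109 by exon length and 84 and 112 by span. Genes with more fragments have narrower intervals and are counted more easily. These shortest and longest classes held 14.4% and 26.9% of wild-type fragments by exon length, and 16.2% and 19.4% by span. The 206 small nucleolar RNAs had a median of -0.16, where random lists of matched abundance had a median of 0.37. The 418 transcribed pseudogenes (median -0.02, percentile 0) and the 156 microRNA genes (-0.01, percentile 0.09) also lay below matched random lists. Those random lists had medians of 0.22 and 0.46, whereas 50.96% and 51.28% of the genes of these classes lay below 0. Their low percentiles thus came from the positive medians of genes of matched abundance. Of the pseudogenes 19 were beyond 2-fold higher and 6 lower, of the microRNA genes 1 and 0, and of the small nucleolar RNAs 0 and 0. The 460 long non-coding RNAs, with a median of 0.24 at percentile 75.8, lay inside the range.

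**Figure D4:**
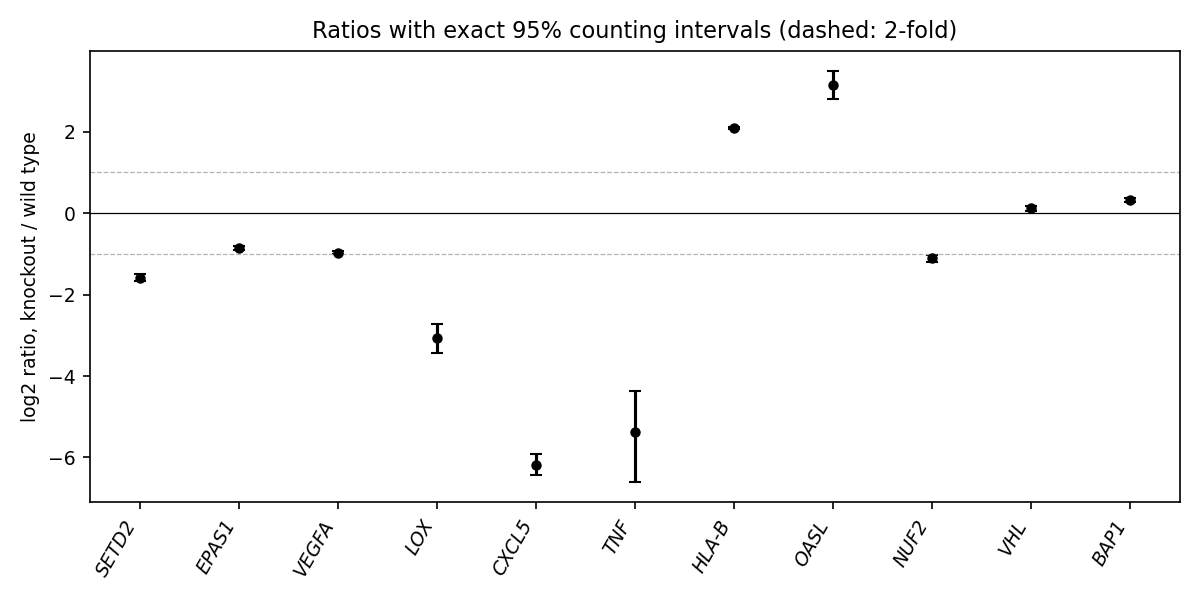
Log2 ratio of knockout to wild type (vertical axis) for 11 named genes, 1 library per line. Points are ratios, bars exact 95% counting intervals and dashed lines 2-fold; SETD2 lies at -1.58 and CXCL5 and TNF lie lowest.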

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

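The ratios relative to neighbouring genes and the undivided counts were chosen only after the data were seen; the other alternatives were planned. The log2 ratio of SETD2 was between -1.59 and -1.51 under every scaling and prior count tried and -1.55 relative to neighbouring genes. The number of genes higher in the knockout library was 971, and between 770 (99% interval) and 1361 (undivided counts) under the alternatives other than the fold alone, which gave 2278. The number of genes lower in the knockout library was 569, and between 417 (relative to neighbouring genes) and 706 (undivided counts) under those alternatives, while the fold alone gave 1316. The fold alone counts scarce genes whose intervals reach inside 2-fold. Total count scaling shifted each log2 ratio by 0.0762, and the other scalings tried on the same genes by less. For 149 named genes, no called ratio changed sign under another scaling, another prior count or relative to neighbouring genes. Called ratios lie beyond 1.5-fold, so scaling shifts of at most 0.0762 could not turn their sign, and that part is no check. The statement concerns the sign only. The sizes were less stable, and relative to neighbouring genes many named ratios in the lower stretches shrank, as given above. Under the 3 other scalings, all 42 lists kept their place inside or outside the range of random lists. Another scaling shifts listed and random genes by the same amount, so it could hardly change that place and is no check of the lists. The list of collagens and extracellular matrix changed direction, with a mean of -0.1388 against its median of 0.36. Of its 30 measured members, 9 were higher and 10 lower, and the cause of the change was not tested. As means, 5 lists moved outside the range (epithelial, proximal tubule, YAP target, long non-coding and cancer-testis genes) and 5 to the inside (collagens, distal nephron genes, stress response, histone genes and ribosomal proteins). The medians of the cholesterol and cancer-testis lists, inside the range in either case, turned sign relative to neighbouring genes. Relative to neighbouring genes, 4 moved outside (renal carcinoma drivers, proximal tubule, YAP target and long non-coding genes) and 3 inside (glycolysis enzymes, histone genes and ribosomal proteins). With at least 50 reads, receptor tyrosine kinases lay inside the range at a median of -0.11 and proximal tubule genes outside it at -0.33, with at least 1 read the distal nephron and histone lists lay inside it, and with 10 bins YAP targets lay outside it; the causes were not tested. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Alternatives planned for tables without counts and for chromosome arms were not run. Depth limits mainly scarce genes, since 3 fragments were 0.0494 and 0.0577 CPM.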

Other observations

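The gene families and single genes named up to the chromosome 9 pair and both tests of genes near 0 in one library were chosen only after the result was seen. Families were formed from the letters that begin gene symbols. Of 406 families with at least 6 measured genes, 53 had a median outside the central 95% of matched random lists. By chance, 20.3 would be expected if the members of a family varied independently, which related or adjacent genes need not do. Pregnancy-specific glycoproteins, secreted proteins of the placenta, were higher, with 9 of 10 PSG genes counted as higher, by an interval wholly beyond 1.5-fold, and a median log2 ratio of 4.28. PSG1, PSG3, PSG5 and PSG9 had 15, 8, 13 and 16 wild-type fragments and 722, 177, 297 and 221 knockout fragments. These genes lie next to each other on chromosome 19 and are nearly identical, so they are not 10 independent observations. Sodium channel genes (SCN) had a median of 2.80, with 6 of 9 higher and 2 lower, and cadherin genes (CDH) a median of 1.49, with 8 of 19 higher and 3 lower. CDH13 and CDH11 were among the lower cadherins, at ratios of 0.0890 and 0.138. Cytochrome P450 genes (CYP) had a median of 1.25, with 14 of 38 higher and 3 lower.

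Chemokines of the CXCL family and metallothioneins had lower medians, though not every member was lower. Of 8 CXCL genes, 5 were lower by the same rule and 0 higher (median -1.64), and of 9 metallothionein genes (MT) 4 were lower and 0 higher (median -1.36). The abundant MT2A and MT1E had ratios of 0.774 and 0.863, while MT1G had 0.120. Of 7 binding proteins of insulin-like growth factors, 4 were lower and 1 higher. IGFBP4 had a ratio of 0.0492 and IGFBP3 a ratio of 0.414, whereas IGFBP7 was 2.16-fold higher. Of MHC class II genes, HLA-DPA1 had 5 and 48 fragments and HLA-DRA 3 and 33 (interval 4.03 to 65.4), whereas HLA-DPB1 had 9 and 5 (ratio 0.648, interval 0.171 to 2.15) and HLA-DMB 11 and 8 (ratio 0.848, interval 0.296 to 2.32). Their regulator CIITA had 14 and 47 fragments, a ratio of 3.92 (interval 2.12 to 7.70), and the invariant chain CD74 had a ratio of 1.60.

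A pair of neighbouring cell cycle inhibitors on chromosome 9 had few fragments in either library. CDKN2A had 1 and 20, a ratio of 23.3 (interval 3.73 to 967) that counts as higher in the knockout library, and CDKN2B had 0 and 1, whereas the flanking genes MTAP and DMRTA1 had 4860 and 559 in the wild-type and 4522 and 772 in the knockout library.

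Genes of stretches of chromosomes 1, 7 and 12 were lower together in the knockout library. After correction for GC content, exon length and abundance the median of 1660 of these genes was -0.5585 (bootstrap range -0.59 to -0.54), against -0.54 before it. That the median hardly moved argues against such a bias as the whole cause. The bootstrap drew genes as if independent, from stretches chosen by these same ratios, so its range understates the uncertainty. A lower copy number in the knockout line and a regional effect of SETD2 loss stay open as explanations and were not tested, since DNA was not analysed here and each line has 1 library.

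Interferon-stimulated genes were higher in the knockout library, by a median log2 ratio of 0.75 over 33 genes. Leukocytes in the knockout sample would bring their transcripts. The median of 18 leukocyte markers there was 0.03845 CPM, but only 9 were measured and the others were entered as 0. That median therefore says little about the abundant markers. The most abundant, LCP1 and CD68, were at 277 and 39.6 CPM in the knockout and at 50.9 and 38.6 CPM in the wild-type library. The markers belong to several leukocyte types, so a contribution of 1 type was not excluded. The shifts of chromosome stretches do not account for the interferon result, since the median relative to neighbouring genes was 0.9946 of the unadjusted one. Loss of SETD2 is a candidate explanation, and so is a difference between the cultures or between clones, and with 1 library per line neither was tested.

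Several genes were near 0 in one library and abundant in the other, with at most 3 fragments against at least 100. Of these, 18 were near 0 in the knockout library, among them ULK2, GSTM4 and IGFBP1, and 13 near 0 in the wild-type library, among them COL22A1, KRT16 and KLK6. Other cells mixed into 1 of the samples would leave few such genes in one direction, and the smaller number, 13, argues against that as the whole cause. Deletions that remove several genes could account for part of those near 0 in the knockout library, where 5 of 16 with expressed neighbours, a share of 0.3125, had a neighbour within 500 kb whose interval lay wholly below 0.25-fold. The 5 were H1F0 (2 of 22 expressed neighbours), PICK1 (2 of 21), ADM2 (1 of 22), MT1L (1 of 13) and MLPH (1 of 4). Most of their neighbours were thus not that low. H1F0 and PICK1 lie within 500 kb of each other, so the 5 are not all separate loci. No share for other genes was computed, and a gene with many neighbours meets the rule more easily. The share therefore cannot decide on such deletions. Deletion and silencing of single genes cannot be told apart here without DNA data.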
